A study of Mus musculus with 5 samples.

How the data were processed

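RNA from whole kidneys of mice aged 8 weeks was sequenced in 5 libraries, 3 labelled as uninduced controls (control 0, 1 and 2) and 2 labelled as Pkd1 knockouts (knockout 0 and 1). The genotype label was used for the groups. The mutants are called SKO in the sample titles and PkdTKO in the series' design text, and neither source explains these names. Per the labels' protocols, total RNA was extracted with TRIzol and 1 µg went into a library made with an Illumina mRNA-seq kit. The labels do not say whether each library came from a separate animal, so every p-value measures only the spread between these samples, which may be technical.

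The deposited table holds FPKM, fragments per kilobase of transcript scaled to the number of mapped fragments, as computed by the authors, with 1 column per library. Per the submitters' processing notes, bcl2fastq and the mm10 genome build were used. The aligner, the program that computed FPKM, the gene annotation and the strandedness of the counting are not given in the sources used here. The table has 23997 rows named by gene symbol. Of these, 22627 rows (94.3%) carry a symbol that occurs once in GENCODE M21, the annotation of the same build that was used here for positions and transcript lengths. A spreadsheet program had turned 27 of the identifiers into dates, 2 of which occur on more than 1 row, and these were never named. No value column was left without a library (0 unmapped).

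Because FPKM are not counts, no count test was run. Differences were computed on log2(FPKM + 1) for the 12640 rows with a mean FPKM of at least 1 over the 5 libraries, so a fold change is on that scale and understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. All adjusted p-values of single genes come from this limma test unless another fit is named. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 31 lists. Each list was also tested with an estimated correlation and with fry, whose main p asks whether a list's genes move one way on balance. For single genes the exact permutation test of 3 against 2 libraries cannot give a p below 0.1. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

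The groups, the tests, the alternatives and the gene lists were fixed before the data were examined. The fixed rule for named genes took Adamts1 and Pkd1, then the 8 largest rises and the 8 largest falls in fitted log2 fold change among genes with an adjusted p under 0.05 and no overlap between the groups, passing over predicted gene models, then up to 4 members of each list tied to the study's question and up to 3 of each other list, by adjusted p. The same rule was applied again with the genes listed at 0 left out, a choice made after seeing the data. Havcr1, Lcn2, Mki67, Col1a1, Hbb-bs, Slco1a1, Prlr, Miox and the further members of the lists that passed were named after their values were seen. Some genes that the rule takes are not reported here. The lists covered metalloproteinases and their inhibitors, basement membrane and its receptors, interstitial matrix, cystic disease genes, injury, cell division, metabolism, signalling, complement, interferon and cell types of the kidney and of neighbouring tissues. Another 3 lists (sex chromosome genes, androgen-dependent and female-biased kidney genes) served only to look for differences between the libraries other than genotype.

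Exact zeros needed care. In 87 tested rows at least 1 library was listed at exactly 0, and abundant genes that every cell uses, such as Gapdh, were among them. Such values may be failed estimates, so each library's value is given for these genes, with no fold. They stayed in the main test, as fixed, and an alternative chosen after seeing the data left them out, which left 12553 rows. Also chosen after seeing the data were a fit with the share of female RNA, estimated from 4 Y-linked genes, as a covariate, and the removal of each library in turn together with the genes listed at 0. That share was 0 in each control, so the covariate fit extrapolates the difference between the 2 knockout libraries and does not separate sex from genotype. In knockout 0 the Y-linked genes gave a share of 0.609, whereas Xist was at 38.3% of its level in knockout 1. The covariate fit used only the Y-linked estimate, so its values are uncertain. The other alternatives were a pseudocount of 0.1, no filter or a mean FPKM of at least 5, rescaling of each library to a common sum (TPM), median-of-ratios scaling, quantile normalization, no variance trend, robust variances, the replicate number as a block, each library left out in turn, an at least 2-fold change, and an adjusted p under 0.1.

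Depth is not stated with the FPKM. In genes with a single transcript of 900 to 5000 bases the smallest non-zero values have a common step, and if that step is 1 fragment, 1 fragment in a transcript of 1 kilobase stood for an FPKM of 0.00646, 0.00594 and 0.00966 in control 0, 1 and 2, and of 0.0114 and 0.0049 in knockout 0 and 1. A smaller step means a deeper library, and the deepest, knockout 1, was then 2.32 times as deep as the shallowest, knockout 0. These figures are estimates, since the effective transcript length used by the authors is not given. Reads shared between near-identical family members, such as the Cyp2d, Cyp4a, Ugt1a, Ly6, Slc22a and haemoglobin genes, or between overlapping genes, could have been split by the authors' program, so values within such families are uncertain.

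The limma step was tested on simulated data for 12553 genes and the same group sizes, with 200 changed genes in each of 10 runs. It recovered 86.7% of the 2-fold and 94.8% of the 4-fold changes. Of the called genes 6.73% were false, and 4.9% of the unchanged genes had an unadjusted p under 0.05. The simulation gave each library the same spread and both knockout libraries the same change. In the data the median absolute log2 difference was 0.18 between the knockout libraries and 0.0787 to 0.109 between controls. These rates therefore need not hold for these libraries.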

Results

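Whole-kidney transcripts were compared between 3 control libraries and 2 libraries labelled as Pkd1 knockouts, all from mice aged 8 weeks. Pkd1 encodes polycystin-1, a membrane protein whose loss causes cystic kidneys. The series addressed the part played by metalloproteinases in remodelling of the tubule basement membrane and in the widening of tubules into cysts, with Adamts1, a secreted metalloproteinase with thrombospondin motifs, in its title. FPKM summed to between 504914.2 and 507052.8 in the controls, to 493226.2 in knockout 0 and to 462814.3 in knockout 1, and each library had between 12324 and 12750 rows with an FPKM of at least 1. Over the 12640 tested rows the Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.9885 to 0.9904 between controls. It was 0.9605 between the knockout libraries and 0.9274 to 0.9464 between a control and a knockout library.

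Pkd1 transcripts were not detectably lower in the libraries labelled as knockouts. Pkd1 had an FPKM of 3.22, 3.51 and 3.49 in control 0, 1 and 2, 2.72 in the library labelled knockout 0 and 3.60 in the library labelled knockout 1. The fitted log2 fold change was -0.09 (SE 0.116, 95% interval -0.38 to 0.20, limma adjusted p = 0.646), and the exact permutation p was 0.7. Without the library labelled knockout 0 the log2 difference was positive, 0.063. A value over the whole gene (ENSMUSG00000032855.6, mm10 chromosome 17, 24549834 to 24596508, plus strand) need not show a loss of single exons or a loss in some cells. It therefore does not settle the label of either library, and every direction below is that of libraries labelled as knockouts, called knockout 0 and knockout 1 for short.

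The sex chromosome genes differed between the libraries. Xist, the transcript that silences an X chromosome in females, had an FPKM of 0.0275, 0.0222 and 0.0257 in the controls, 30.8 in knockout 0 and 80.3 in knockout 1. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d averaged 39.1% of their control mean in knockout 0 and 0.0234% in knockout 1. Ddx3y had an FPKM of 18.1 ± 0.423 (SD, n = 3) in the controls, 7.30 in knockout 0 and 0.00194 in knockout 1. Of the 5 tested sex chromosome genes Xist rose, and adjusted over the list alone the 4 Y-linked genes fell as well. The controls thus held Y-linked RNA and hardly any Xist, knockout 1 the reverse, and knockout 0 both. The labels do not say whether knockout 0 came from 1 animal. No control library was without Y-linked RNA, so no comparison of the groups below holds the sex of the RNA constant.

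**Figure D1:**
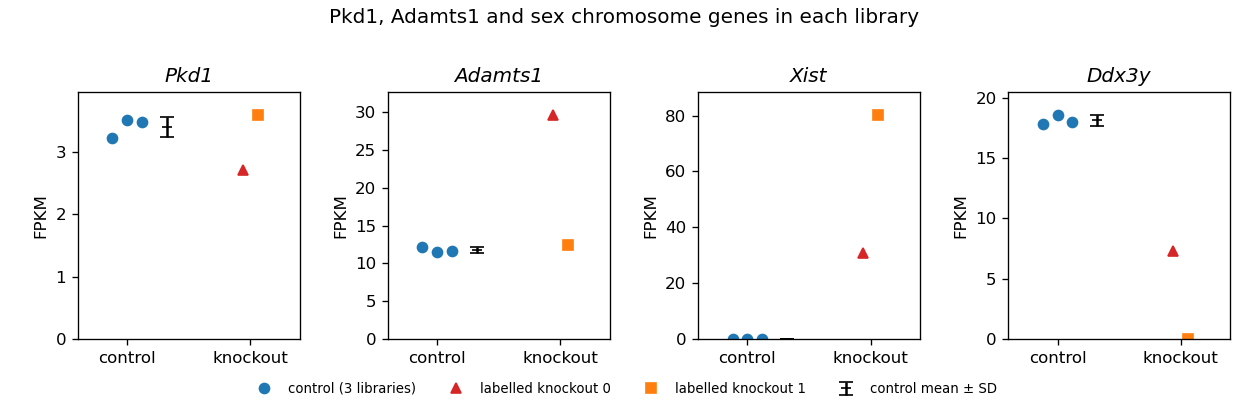
FPKM (linear axes from 0) of Pkd1, Adamts1, Xist and the Y-linked gene Ddx3y in each of the 5 libraries, with the mean ± SD of the 3 controls. Pkd1 was 3.60 in the library labelled knockout 1, above every control, and Ddx3y was 7.30 in knockout 0 and 0.00194 in knockout 1.

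In both libraries labelled as knockouts, the median difference from the controls was positive for transcripts of basement membrane proteins, of their receptors and of immediate early transcription factors, and negative for those of fatty acid oxidation and of the mitochondrial respiratory chain. Over all genes 4 of 31, 5 of 19, 8 of 13, 5 of 24 and 3 of 28 tested members of these lists passed in that direction, and the camera calls of the lists were lost with an estimated correlation (adjusted p = 0.302, 0.261, 0.261, 0.354 and 0.302). Itga6, an integrin subunit that binds laminin, rose from 30.45 ± 1.63 (SD, n = 3) in the controls to 67.8 and 78.9 in knockout 0 and 1. Egr1, an immediate early transcription factor, rose from 6.48 ± 1.05 to 22.6 and 24.3. Eci1, an enzyme of mitochondrial fatty acid oxidation, fell from 186.1 ± 12.4 to 117.4 and 116.4. Macrophage, cell division, interstitial matrix and tubule injury genes had median log2 differences from the controls of 1.95, 1.16, 1.14 and 1.38 in knockout 0, and of 0.40, 0.19, 0.17 and 0.05 in knockout 1.

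In all, 802 of 12640 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05), 345 higher and 457 lower in the knockout libraries, and 193 of them differed at least 2-fold. Rescaled to TPM the split was 454 higher and 266 lower of 720, and with the genes listed at 0 left out it was 336 higher and 479 lower of 815. With the replicate number as a block 28 genes passed, 25 higher and 3 lower. The groups did not overlap in 6089 genes (48.2%), against 20% by chance. The count of 802 was 37, 155 and 36 without control 0, 1 and 2, 1054 without knockout 0 and 2599 without knockout 1. With the genes listed at 0 left out as well, limma called 0 genes without control 0 and 0 without control 2, where 2393 and 2147 had an unadjusted p under 0.05.

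Genes listed at 0 made up the largest differences. The 8 largest positive ones were all listed at 0 in the 3 controls. They were Fth1 (FPKM 4168 in knockout 0 and 3114 in knockout 1) and Ftl1 (3082 and 2981), which encode ferritin chains, Napsa (1718 and 2289), Atp5b (1597 and 1551), Klk1 (1481 and 1622), Slc27a2 (1204 and 1138), Tmbim6 (1035 and 981.6) and Gapdh (1073 and 853.6). Spp1, osteopontin, had an FPKM of 645.8, 1003 and 718.2 in control 0, 1 and 2, and was listed at 0 in both knockout libraries. In all, 22 genes other than small RNAs were listed at 0 in every control and above 0 in both knockout libraries. They included Umod (784.3 and 1144 in knockout 0 and 1), Timp3 (604.8 and 596.5) and Mep1a (541.7 and 521). Since Gapdh, which every cell uses, was among them, no direction was drawn from these values.

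With the genes listed at 0 left out, the largest rise was that of Ugt1a2, a glucuronosyltransferase that shares exons with its neighbours, so its value is uncertain. Its FPKM was 0.687, 20.0 and 8.07 in control 0, 1 and 2, and 337.1 and 675.4 in knockout 0 and 1 (log2 fold change 6.13, SE 1.06, limma adjusted p = 0.0357 over 12553 genes). Xist followed (log2 5.63, adjusted p = 0.0112). Serpina6, the corticosteroid-binding globulin, rose from 0.0223 ± 0.00223 (SD, n = 3) to 18.4 and 11.4, and Fabp1, a fatty acid binding protein, from 1.00 ± 0.552 to 12.0 and 43.3. Abcc3, an organic anion exporter, rose from 0.979 ± 0.172 to 18.1 and 24.2 (adjusted p = 0.00456). Mid1, which lies on the X chromosome, rose from 5.34 ± 0.570 to 37.4 and 59.97, Ly6f from 1.04 ± 0.311 to 15.9 and 11.6, and the complement component C3 from 2.59 ± 0.144 to 39.7 and 12.6. Among the falls, the oxysterol hydroxylase Cyp7b1 had an FPKM of 115.3, 20.7 and 73.7 in control 0, 1 and 2, and of 4.05 and 1.80 in knockout 0 and 1 (log2 -3.93, SE 0.736, adjusted p = 0.0411). Bcat1, a branched-chain aminotransferase, fell from 11.75 ± 3.89 to 1.101 and 0.793, and Upp2, a uridine phosphorylase, from 10.04 ± 0.886 to 1.02 and 0.881 (adjusted p = 0.00456). Inmt, an indolethylamine methyltransferase, fell from 897.2 ± 74.2 to 260.1 and 139.9, and the apolipoprotein gene Apoa4 from 15.2 ± 1.47 to 2.06 and 3.51. Cyp2d12, Cyp2d9 and Slc22a28 fell by 2.48, 2.33 and 2.37 on the log2 scale. Slc22a28 passed only with the genes listed at 0 left out (adjusted p = 0.0497, against 0.0542 over all genes), and all 3, like Ly6f, have near-identical relatives that make their values uncertain. Of 62 named genes and list members that passed, 5, 17 and 4 still passed without control 0, 1 and 2. After quantile normalization 44 still passed, and with the replicate number as a block 4 did.

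Adamts1 was higher than every control in both knockout libraries, by a wide margin in knockout 0 and a narrow one in knockout 1. Its FPKM was 12.2, 11.5 and 11.7 in control 0, 1 and 2, 29.7 in knockout 0 and 12.4 in knockout 1. The log2 fold change of 0.66 (SE 0.337, 95% interval -0.18 to 1.51) did not pass (limma adjusted p = 0.253). The exact permutation p was 0.1, the smallest that 3 against 2 libraries allow. Adamts1 shares this lack of overlap between the groups with 48.2% of all tested genes. Against the same controls, knockout 0 alone gave a log2 difference of 1.26 (adjusted p = 0.00233) and knockout 1 alone 0.067 (adjusted p = 0.547). With the share of female RNA as a covariate the log2 fold change was 3.13 (adjusted p = 0.00405), a value set by the difference between the 2 knockout libraries, since that share was 0 in each control. Over all alternatives the adjusted p ranged from 0.000755 to 0.586. A fit with 1 knockout library assumes that it varies like the controls, and the difference between the 2 knockout libraries was not tested here or for any gene below. Adamts1 (ENSMUSG00000022893.14) lies on mm10 chromosome 16 from 85793827 to 85803113, minus strand.

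Among the 9 tested members of the ADAMTS and ADAMTS-like family 0 rose and 1 fell, over all genes and adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Adamts15 fell from 7.76 ± 1.93 (SD, n = 3) to 3.46 and 2.96 (log2 -1.04, SE 0.196, limma adjusted p = 0.0461). Adamtsl4 was at 0.956 ± 0.195 in the controls and 2.95 and 1.47 in knockout 0 and 1, and Adamts5, an aggrecan-cleaving enzyme, at 3.14 ± 0.751, 5.68 and 3.82. The family did not pass as a list (camera adjusted p = 0.456), though knockout 0 alone gave 0.0353, and knockout 1 alone pointed lower (0.682). Of 7 tested matrix metalloproteinases 0 passed over all genes by limma, with 2 higher at an unadjusted p under 0.05, and 1 rose adjusted over the list alone. That 1 was Mmp14, a membrane-bound enzyme that activates Mmp2, at 3.84 ± 0.523 in the controls and 14.3 and 6.97 in knockout 0 and 1 (adjusted p = 0.0683). Mmp11 was at 2.79 ± 0.220, 4.58 and 3.34, and Mmp12, an elastase of macrophages, at 0.311 ± 0.0305, 3.78 and 0.541. The matrix metalloproteinase list was higher by camera (adjusted p = 0.036, or adjusted p = 0.52 with an estimated correlation). It did not pass when rescaled to TPM (0.0646), after quantile normalization (0.118), without control 0 (0.0584) or without knockout 0 (0.304).

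Bmp1, the procollagen C-proteinase, rose from 3.08 ± 0.585 (SD, n = 3) to 7.44 and 6.89 (log2 1.01, SE 0.137, limma adjusted p = 0.026). Among the 8 tested ADAM and astacin metalloproteinases the other that passed was Mep1a, listed at 0 in the controls, and none fell. Adjusted over the list alone Bmp1 and Mep1a were called higher and Mep1b, a meprin subunit, fell, at 130.2 ± 22.2, 73.9 and 78.8. Adam10, a sheddase, was at 24.4 ± 0.839, 32.6 and 26.9. Among 6 tested inhibitors Timp3, listed at 0 in the controls, was the only one to pass, and adjusted over the list alone 2 did, the other being Timp2 at 15.5 ± 0.872, 30.0 and 20.8. Timp1 was at 0.4003 ± 0.155 in the controls, 18.96 in knockout 0 and 0.879 in knockout 1. The ADAM and astacin list and the inhibitor list were called higher by camera (adjusted p = 0.028 and 0.0167, or adjusted p = 0.52 and 0.302 with an estimated correlation). Neither was called with the genes listed at 0 left out (0.322 for each), and the inhibitor list was not called with no filter on low values (0.0599). The ADAM and astacin list was not called without control 1 (0.064), without knockout 0 (0.172) or at a mean FPKM of at least 5 (0.113).

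The basement membrane list had a median log2 difference of 0.29 in knockout 0 and 0.17 in knockout 1, with 21 and 23 of 31 tested members above every control and 7 and 4 below every control. Of the 31 members 4 rose, 0 fell and 27 did not pass over all genes by limma (2 were lower at an unadjusted p under 0.05), and adjusted over the list alone 8 rose and 1 fell. Lamb1 and Lamc1, laminin chains, rose from 30.8 ± 0.773 (SD, n = 3) to 46.7 and 45.5 and from 8.43 ± 0.550 to 13.97 and 13.05. Npnt, nephronectin, a ligand of an integrin needed for kidney development, rose from 78.6 ± 6.12 to 139.6 and 161.5 (log2 0.93, SE 0.107, adjusted p = 0.0198), and Frem2 from 2.44 ± 0.152 to 3.72 and 4.12. The list was higher by camera (adjusted p = 0.000149, or adjusted p = 0.302 with an estimated correlation), with 0.00129 for knockout 0 alone and 0.00286 for knockout 1 alone. Of 19 tested receptors of the basement membrane 5 rose and 14 did not pass, and 12 rose adjusted over the list alone. They were Itga6 (log2 1.24, SE 0.0952, adjusted p = 0.00778), Itga1, which rose from 9.85 ± 0.394 to 16.1 and 18.8, the collagen receptor Ddr2, Itgav and Itga3. The receptor list was higher by camera (adjusted p = 5.25e-06, or adjusted p = 0.261 with an estimated correlation).

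Interstitial matrix genes had a larger median log2 difference in knockout 0 (1.14) than in knockout 1 (0.17). Of 24 tested members 0 passed by limma, over all genes or adjusted over the list alone, with 6 higher at an unadjusted p under 0.05, and all 24 had a positive log2 fold change. The proteoglycan genes Bgn and Dcn were at 53.7 ± 4.45 (SD, n = 3) in the controls, 133.8 and 80.5 in knockout 0 and 1, and at 21.01 ± 3.37, 27.0 and 35.1. Thbs2 was at 0.971 ± 0.115, 3.33 and 1.52, and the collagen gene Col1a1 at 10.3 ± 3.31, 41.2 and 10.2. The list was higher by camera (adjusted p = 3.61e-05, or adjusted p = 0.52 with an estimated correlation), with 0.0625 without knockout 0.

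Of 25 tested cystic disease and ciliary genes 2 rose, 2 fell and 21 did not pass, and the counts were the same adjusted over the list alone. Glis2, a transcription factor mutated in nephronophthisis, rose from 65.0 ± 6.84 (SD, n = 3) to 108.5 and 105.4, and Pkhd1, which encodes fibrocystin, from 14.9 ± 1.12 to 19.95 and 21.6. Tulp3, which carries membrane proteins into cilia, fell from 19.65 ± 0.173 to 13.9 and 11.3, and Ift20 from 54.8 ± 1.96 to 38.8 and 42.3 (limma adjusted p = 0.0307, 0.0471, 0.0343 and 0.041). The list did not pass by camera (adjusted p = 0.98, pointing higher, while its median was -0.03).

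**Figure D2:**
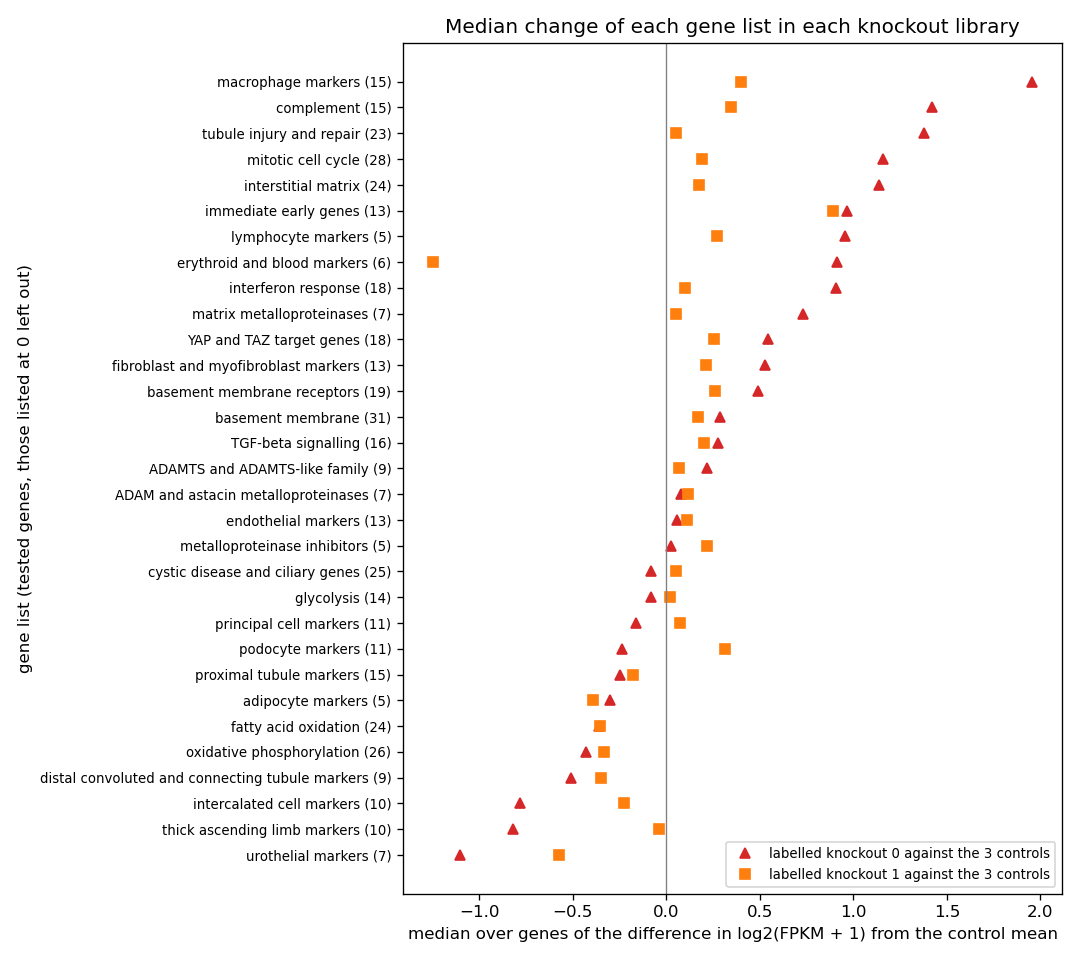
Median over the tested genes of each list of the difference in log2(FPKM + 1) from the mean of the 3 controls, for each knockout library, with genes listed at 0 left out and the number of genes in brackets. Macrophage markers had a median of 1.95 in knockout 0 and 0.40 in knockout 1, and immediate early genes 0.97 and 0.89.

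Genes of tubule injury and repair stood far above the controls in knockout 0. Havcr1, the injury marker KIM-1, had an FPKM of 1.12, 0.975 and 0.718 in control 0, 1 and 2, 137.4 in knockout 0 and 0.593 in knockout 1. Lcn2, which encodes NGAL, had 5.30, 6.86 and 4.76 in the controls, 132.2 in knockout 0 and 4.87 in knockout 1. Neither passed in the test of both libraries (limma adjusted p = 0.326 and 0.322). Of 24 tested members 4 rose and 19 did not pass, and 4 rose adjusted over the list alone. They included Sox4, which rose from 6.70 ± 0.762 (SD, n = 3) to 14.6 and 12.3, the ferroxidase ceruloplasmin Cp, from 8.89 ± 0.968 to 33.4 and 19.1, and the cell cycle inhibitor Cdkn1a. The remaining member, Spp1, was listed at 0 in both knockout libraries and was called lower in both counts. The camera adjusted p of the list was 0.000726 (adjusted p = 0.563 with an estimated correlation), and 0.276 without knockout 0.

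Cell division genes were higher in knockout 0. Of 28 tested mitotic genes 0 passed by limma, over all genes or adjusted over the list alone, with 6 higher at an unadjusted p under 0.05. Mcm4, a replication helicase subunit, was at 2.895 ± 0.295 (SD, n = 3) in the controls, 6.29 in knockout 0 and 4.06 in knockout 1, Rrm2, a ribonucleotide reductase subunit, at 4.39 ± 1.37, 13.6 and 6.53, and Mki67, a marker of dividing cells, at 1.68 ± 0.653, 5.70 and 2.29. The list had a camera adjusted p of 1.2e-05 (adjusted p = 0.534 with an estimated correlation), and of 0.163 without knockout 0.

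All 15 tested macrophage markers lay above every control in both knockout libraries. None passed singly in the limma test, over all genes or adjusted over the list alone (0 of 15, with 10 at an unadjusted p under 0.05). Cx3cr1, a chemokine receptor, was at 1.63 ± 0.0156 (SD, n = 3) in the controls, 6.63 in knockout 0 and 3.19 in knockout 1, Lyz2, a lysozyme, at 15.7 ± 2.23, 102.5 and 32.9, and the protease gene Ctss at 11.3 ± 0.816, 67.5 and 19.95. The list was higher by camera (adjusted p = 1.1e-05, or adjusted p = 0.52 with an estimated correlation) and in knockout 1 alone (6.65e-06). Of 5 tested lymphocyte markers 0 passed by limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, and Cd3g was at 0.594 ± 0.105, 2.62 and 1.11. The lymphocyte list had a camera adjusted p of 0.0148 (adjusted p = 0.52 with an estimated correlation), and of 0.0625 without knockout 0. Of 15 tested complement genes 2 rose and 13 did not pass, and 7 rose adjusted over the list alone. C2 rose from 18.6 ± 1.22 to 51.5 and 46.1, C3 rose as given above, and Serping1, an inhibitor of C1, was at 29.3 ± 2.43, 45.2 and 38.5. The complement list was higher by camera (adjusted p = 5.25e-06, or adjusted p = 0.52 with an estimated correlation). Of 18 tested interferon-response genes the guanylate-binding protein Gbp3 rose, from 4.94 ± 0.418 to 22.97 and 14.2, over all genes and adjusted over the list alone. Ifit2 was at 5.24 ± 0.341, 12.7 and 7.72. The interferon list had a camera adjusted p of 7.55e-05 (adjusted p = 0.52 with an estimated correlation), and of 0.104 without knockout 0.

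Immediate early genes had a median log2 difference of 0.97 in knockout 0 and 0.89 in knockout 1, with 12 of 13 above every control in each. Of the 13 tested members 8 rose and 5 did not pass, and 9 rose adjusted over the list alone. They were Egr1 (log2 1.72, SE 0.134, limma adjusted p = 0.00783), Zfp36, which rose from 24.3 ± 1.59 (SD, n = 3) to 48.2 and 52.2, Fos, from 1.403 ± 0.350 to 7.54 and 11.2, Btg2, Jun, Ier2, Junb and Nr4a1. The list had a camera adjusted p of 4.93e-08 (adjusted p = 0.261 with an estimated correlation), the smallest of the 31 lists. Of 18 tested targets of YAP and TAZ, coactivators that respond to cell stretch and density, 3 rose and 15 did not pass, and 8 rose adjusted over the list alone. Myof rose from 6.39 ± 0.839 to 15.9 and 15.5, Amotl2 from 29.5 ± 1.52 to 47.65 and 40.4, and Asap1 from 4.06 ± 0.303 to 5.75 and 6.13. The YAP and TAZ list was higher by camera (adjusted p = 5.13e-05, or adjusted p = 0.27 with an estimated correlation). Of 16 tested genes of TGF-beta signalling 0 passed by limma, over all genes or adjusted over the list alone, with 5 higher at an unadjusted p under 0.05. Ltbp4, which binds latent TGF-beta, was at 9.82 ± 0.558 in the controls, 12.4 in knockout 0 and 13.97 in knockout 1, and Tgfb2 at 0.704 ± 0.0591, 2.19 and 1.29. The TGF-beta list was higher by camera (adjusted p = 0.00218, or adjusted p = 0.302 with an estimated correlation).

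**Figure D3:**
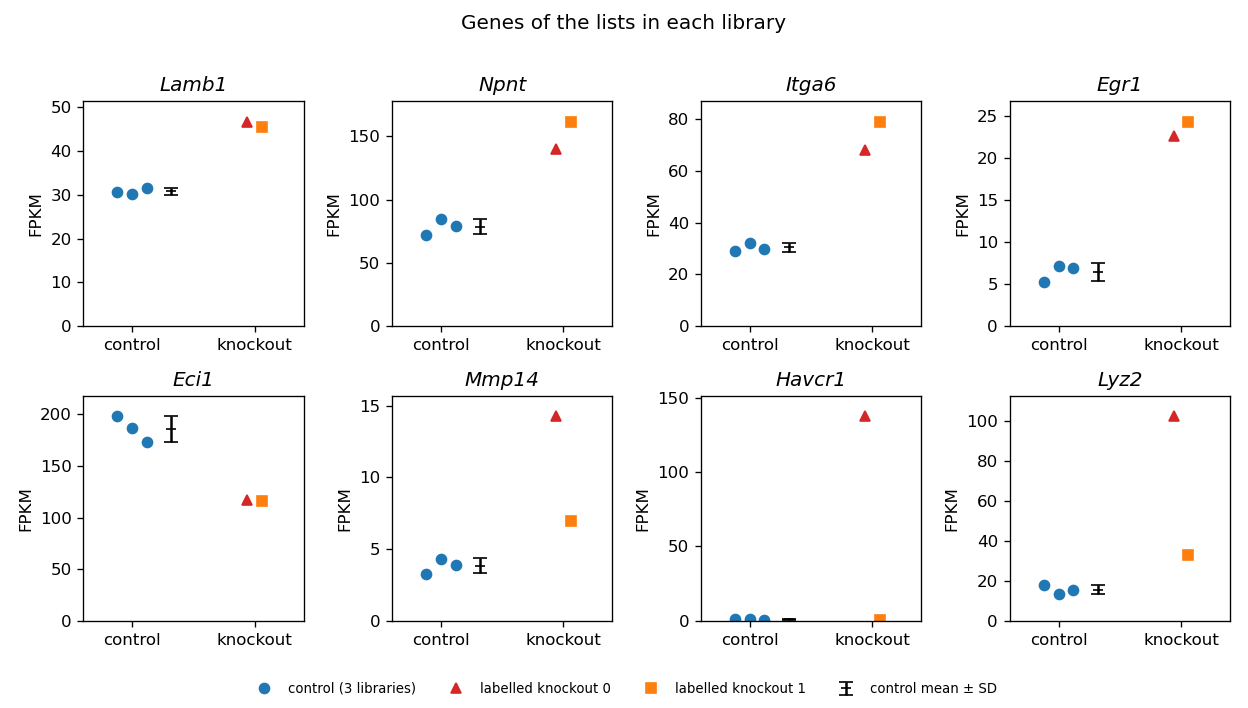
FPKM (linear axes from 0) of 8 genes in each of the 5 libraries, with the mean ± SD of the 3 controls. Lamb1, Npnt, Itga6 and Egr1 were higher and Eci1 lower in both knockout libraries, whereas Havcr1 was 137.4 in knockout 0 and 0.593 in knockout 1, and Mmp14, Havcr1 and Lyz2 did not pass the limma test.

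Of 24 tested genes of fatty acid oxidation 5 fell, 1 rose and 18 did not pass, and adjusted over the list alone 12 fell and 2 rose. Acads, the short-chain acyl-CoA dehydrogenase, fell from 122.3 ± 8.67 (SD, n = 3) to 76.2 and 63.8, Hadh from 384.4 ± 21.7 to 232.1 and 271.6, and Eci1, Acadvl and Etfa fell as well. Cyp4a14, an omega-hydroxylase with near-identical relatives, rose from 39.9 ± 5.94 to 103.9 and 255.7, and was the only member of this list to rise over all genes. The list was lower by camera (adjusted p = 0.000331, or adjusted p = 0.354 with an estimated correlation), with a median log2 difference of -0.36 in knockout 0 and -0.35 in knockout 1.

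Of the 28 tested genes of oxidative phosphorylation, Atp5a1 (FPKM 728.3 and 915.9 in knockout 0 and 1) and Atp5b were listed at 0 in the controls. The other 26 all lay below every control in both knockout libraries. Ndufv1, Ndufa4 and Ndufs3, subunits of the respiratory chain, fell from 235.1 ± 5.13 (SD, n = 3) to 169.6 and 169.6, from 1704 ± 56.8 to 1202 and 1150, and from 264 ± 11.6 to 189 and 202. With Atp5a1 and Atp5b called higher, 23 members did not pass, and 24 fell adjusted over the list alone. The list was lower by camera (adjusted p = 1.05e-05, or adjusted p = 0.302 with an estimated correlation), with a median log2 difference of -0.43 in knockout 0 and -0.33 in knockout 1. The fry test pointed higher (adjusted p = 0.00346) with Atp5a1 and Atp5b included and lower with them left out (0.0198). Of 15 tested glycolysis genes Pfkp rose, from 13.3 ± 0.495 to 21.1 and 17.8, Gapdh was listed at 0 in the controls and called higher, and 13 did not pass. Adjusted over the list alone the count was the same, and the glycolysis list did not pass by camera (adjusted p = 0.693, pointing higher, while its median was -0.03), and with Gapdh left out it pointed lower (adjusted p = 0.716, with a median of -0.054).

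Among markers of the nephron segments, Irx1 on the thick ascending limb list fell from 30.3 ± 4.31 (SD, n = 3) to 8.14 and 13.3 (limma adjusted p = 0.0311). Calb1, a calcium-binding protein of the distal tubule, fell from 265.6 ± 21.7 to 100.5 and 148.8, and Fxyd4 of principal cells from 96.9 ± 0.251 to 77.6 and 74.2. Each was the only member to fall among 11, 10 and 11 tested, and adjusted over the list alone 1, 3 and 1 fell. Umod and Klk1, listed at 0 in the controls, were called higher on the thick ascending limb and distal lists. The camera adjusted p-values of these 3 lists were 0.693, 0.429 and 0.532. That of the distal list was 0.0317 with the genes listed at 0 left out (adjusted p = 0.495 with an estimated correlation) and 0.0197 without knockout 1. Of 10 tested intercalated cell markers 0 passed by limma, over all genes or adjusted over the list alone, with 4 lower at an unadjusted p under 0.05. All 10 lay below every control in knockout 0 and 5 did in knockout 1, and the proton pump subunit Atp6v1g3 was at 39.2 ± 5.76, 19.4 and 27.8. The intercalated cell list was lower by camera (adjusted p = 0.00361, or adjusted p = 0.52 with an estimated correlation), with 0.1 without knockout 0.

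Of 18 tested proximal tubule markers Slc27a2, Ass1 (FPKM 155.7 and 321 in knockout 0 and 1) and Cyp4b1 (1143 and 356.8) were listed at 0 in the controls and called higher, and the other 15 did not pass. Adjusted over the list alone, with those 3 included, 5 were higher and 4 lower. Cubn, cubilin, was at 39.8 ± 2.04 (SD, n = 3) in the controls, 50.9 in knockout 0 and 61.1 in knockout 1, and Miox, an oxygenase of the proximal tubule, at 1805 ± 193, 1246 and 1283. The list did not pass by camera (adjusted p = 0.417, pointing higher, while its median was -0.12), and with those 3 left out it pointed lower (adjusted p = 0.29, with a median of -0.30).

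Among the other cell types, 0 of 13 endothelial, 11 podocyte, 7 urothelial and 5 adipocyte markers passed over all genes by limma, and at an unadjusted p under 0.05 there were 2 and 1 higher and 4 and 4 lower. Adjusted over the list alone 4 urothelial and 3 adipocyte markers fell, and none of the endothelial or podocyte markers passed. Pecam1 of endothelium was at 17.2 ± 0.416 (SD, n = 3) in the controls, 21.3 in knockout 0 and 20.3 in knockout 1. Upk3a, a uroplakin of the urothelium, was at 5.57 ± 0.796, 0.858 and 2.47, and Pnpla2, a lipase of fat cells that other tissues also express, at 44.7 ± 1.27, 36.1 and 33.9. The urothelial and adipocyte lists were lower (camera adjusted p = 0.0038 and 0.0104, or adjusted p = 0.52 and 0.302 with an estimated correlation). The endothelial list was higher (adjusted p = 0.028, or adjusted p = 0.302 with an estimated correlation), but not without knockout 1 (0.162), with no filter on low values (0.053) or with the share of female RNA as a covariate (0.918). That covariate also ended the call of the adipocyte list (0.227). The podocyte list was not called (adjusted p = 0.62, pointing higher, while its median was -0.04).

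Of 13 fibroblast and myofibroblast markers the pericyte proteoglycan Cspg4 rose, from 3.29 ± 0.292 (SD, n = 3) to 5.18 and 5.25, over all genes and adjusted over the list alone, and 12 did not pass. Thy1 was at 1.70 ± 0.113 in the controls, 7.46 in knockout 0 and 2.67 in knockout 1. The fibroblast list was higher by camera (limma, adjusted p = 0.0327, or adjusted p = 0.52 with an estimated correlation), but not rescaled to TPM (0.0804), without control 0 (0.116), without knockout 0 (0.0733), at a mean FPKM of at least 5 (0.161) or with no filter on low values (0.0599). Of 6 tested erythroid and blood markers 1 rose and 5 did not pass, while 1 rose and 1 fell adjusted over the list alone. The list was not called by camera (adjusted p = 0.98, pointing lower, with a median of -0.18 and a mean of 0.06). Its median log2 difference was 0.91 in knockout 0 and -1.25 in knockout 1, so the 2 libraries went opposite ways. Hbb-bs, a haemoglobin gene with near-identical copies, was at 3.64, 0.783 and 3.12 in control 0, 1 and 2, 72.3 in knockout 0 and 0.593 in knockout 1. The neutrophil, adrenal, skeletal muscle and pancreas lists had 1, 1, 2 and 1 tested members and were not tested as lists. By limma 0 of these passed over all genes, 1 was lower at an unadjusted p under 0.05, and that 1, Pvalb of the muscle list, which is also a distal tubule gene, fell adjusted over the list alone.

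Genes known to differ between male and female kidneys differed between the groups as well. Of 11 tested androgen-dependent genes 2 fell, Cyp2d9 and Cyp7b1, 0 rose by limma (0 at an unadjusted p under 0.05) and 9 did not pass, and 5 fell adjusted over the list alone. The median log2 difference of this list was -0.50 in knockout 0 and -3.97 in knockout 1. Slco1a1, an organic anion transporter, was at 104.1, 14.2 and 58.0 in control 0, 1 and 2, 31.2 in knockout 0 and 0.0422 in knockout 1. Of 9 tested female-biased genes 4 rose, Abcc3, Slc7a12, which rose from 21.1 ± 5.77 (SD, n = 3) to 107.6 and 181.3, Slc22a29 and Cyp4a14, and 2 fell, Cyp2d12 and Slc22a26. Adjusted over the list alone 6 rose and 2 fell. The prolactin receptor gene Prlr was at 23.5 ± 4.04, 38.7 and 97.4 (adjusted p = 0.0977). With the share of female RNA as a covariate, the log2 fold changes of Cyp2d9 (0.12), Slc22a28 (1.08), Fabp1 (-0.011) and Cyp4a14 (-0.64) turned their sign. Each changed enough more in knockout 1 than in knockout 0 that the fit's extrapolation to a share of 0 turned the sign. A larger change in knockout 1 was not sufficient, since Inmt (log2 -1.78 in knockout 0 and -2.67 in knockout 1) kept its sign.

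Over the lists, camera called 22 of 31, 17 higher and 5 lower, and 21 when the genes listed at 0 were left out. With an estimated correlation 0 of the 31 passed (smallest adjusted p = 0.261, with 4 at an unadjusted p under 0.05). Fry called 14 lists and did not call 11 of the 22, those of matrix metalloproteinases, interstitial matrix, injury, cell division, complement, interferon response and of macrophage, lymphocyte, fibroblast, intercalated and urothelial markers. With the share of female RNA as a covariate camera called 27 lists, 20 of the 22 and 7 others, among them the ADAMTS family (adjusted p = 0.00401). These calls too are set by the difference between the 2 knockout libraries, so they do not hold the sex of the RNA constant. Without knockout 0 camera called 13 lists, and without knockout 1 it called 23. The log2 differences from the controls of the 2 knockout libraries had a Pearson correlation across 12553 genes of 0.559, against 0.245 in 100 simulations of unchanged libraries that share the 3 controls, and a covariance of 0.117 against 0.00973. Genes called higher in both numbered 305, against 55.2 for independent lists, and genes called lower in both 321, against 49.0. In the 100 simulations of unchanged libraries that share the controls, limma called at most 1 gene higher in both and 0 lower in both, but these leave out real effects, as the independent lists leave out the shared controls. Part of this excess may come from the shared controls, which were not split between the 2 libraries. Both knockout libraries also held more Xist and less Y-linked RNA than every control. The overlap thus does not tell a shared sex difference from a shared effect of the labelled knockout.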

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

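Leaving out the genes listed at 0, with or without a further library, and the covariate for the share of female RNA were chosen only after the data were seen, and the other alternatives before. The 802 genes became 193 with an at least 2-fold change, 2044 at an adjusted p under 0.1, 482 with no filter on low values, and 36 to 2599 without 1 library. The first 2 follow from the threshold and the third from more genes tested. Without a control library fewer genes passed, and the part of this due to the smaller number of libraries was not tested. Without a knockout library more passed, which a smaller number of libraries alone does not explain. There the residual spread came from the controls only, so the difference between the knockout libraries did not enter it. The median absolute log2 difference was 0.18 between the knockout libraries and 0.0787 to 0.109 between controls. With the genes listed at 0 left out and 1 library removed, limma called 0 (without control 0 and without control 2, with 2393 and 2147 at an unadjusted p under 0.05), 138 (without control 1), 1710 (without knockout 0) and 3029 genes (without knockout 1). The other alternatives, apart from the replicate block, gave 579 to 1088 genes, and of the 1088 with the covariate only 122 were among the 802.

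The replicate number as a block (replicate block) gave 28 genes, 27 of them among the 802, and ended the call of the fibroblast list (adjusted p = 0.0692) and of no other list. The labels do not say what the number marks. Deviations from the group means correlated at 0.128 for number 0 and 0.0185 for number 1. With 2 knockout libraries the deviations of 1 mirror those of the other, so these values neither show nor exclude pairing. The main fit without a block was fixed beforehand and kept. Control 2 shares its number with no knockout library. The block fit thus gave the same log2 fold changes as the fit without control 2 (Adamts1 0.66, Pkd1 -0.077).

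Adamts1 stayed positive under each alternative, and its log2 fold change ranged from 0.067 to 1.26 without 1 library. It passed without knockout 1 (1.26, with or without the genes listed at 0) and with the covariate (3.13). Pkd1 ranged from -0.245 to 0.063 without 1 library, was positive without knockout 0 (0.063, with or without the genes listed at 0), and gave no value at a mean FPKM of at least 5. With the covariate Pkd1 was at -0.725 (limma adjusted p = 0.105), again a value set by the difference between the 2 knockout libraries. Camera called 13 to 23 lists without 1 library, 14 with the genes listed at 0 left out and without knockout 0, 0 with an estimated correlation (4 at an unadjusted p under 0.05), and fry called 14. With the covariate Cyp2d9 (0.12), Fabp1 (-0.011), Slc22a28 (1.08) and Cyp4a14 (-0.64) reversed. Each of the 4 changed enough more in knockout 1 than in knockout 0 that extrapolation to a share of 0 turned the sign. The turned signs follow from this and say nothing further about sex. Of the other values of 63 named genes and list members over 21 alternatives, 784 kept their direction and side of the threshold, 521 kept the direction and lost the call, and 6 gained it. Depth limits the low genes most, and 1 fragment in a transcript of 1 kilobase was estimated at 0.0049 to 0.0114 FPKM.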

Other observations

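The tests of the higher genes alone, of the genes known to differ by sex, of the injury, matrix, cell division and macrophage genes and of the genes listed at 0, and the choice of the NRF2 list, were made only after the results were seen.

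Abcc3, which NRF2 can induce, was higher in both knockout libraries, but the list of 20 tested NRF2 target genes was not called (camera p = 0.111, pointing lower, or p = 0.23 with an estimated correlation). Of these 0 rose by limma, with 0 higher and 8 lower at an unadjusted p under 0.05, 3 fell and 17 did not pass. Gstm1, a glutathione transferase, fell from 445.8 ± 37.1 (SD, n = 3) to 295.9 and 251.7, Me1, the cytosolic malic enzyme, from 235.3 ± 52.2 to 115.8 and 79.3, and Taldo1, of the pentose phosphate pathway, from 234.7 ± 5.05 to 181.7 and 160.9. These falls go against a rise of the NRF2 targets as a group along with Abcc3. The median log2 difference of the list from the controls was 0.044 in knockout 0 and -0.266 in knockout 1. Hmox1 went opposite ways, at 17.7 ± 2.36 in the controls, 32.4 in knockout 0 and 8.79 in knockout 1. Abcc3 is also on the list of female-biased genes.

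The first pattern is the set of 1704 genes called between knockout 1 and the controls with the genes listed at 0 and the sex chromosome genes left out, for which the sex of the RNA is a candidate explanation. Knockout 0 held Y-linked RNA at 39.1% of the control level, so it may mix RNA of more than 1 animal. A sex difference alone was taken to give it at most a female share of 0.609 of the change in knockout 1. Xist in knockout 0 was at 38.3% of its level in knockout 1, which points to a smaller share, so 0.609 is uncertain. The median over genes was 0.708 (95% bootstrap interval 0.674 to 0.743), and 0.613 (0.57 to 0.70) over the 806 higher genes alone. Over the 898 lower genes it was 0.75. Over 15 of the genes known to differ by sex the median was 0.674, with 9 above 0.609 and a range from -0.471 to 1.01, so the female share was not a ceiling for such genes. Sex and the labelled knockout therefore cannot be told apart for this set, since no control was female.

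The second pattern is the set of injury, matrix, cell division and macrophage genes that were higher in knockout 0. A sex difference alone was taken to make the change at least as large in knockout 1, the library without Y-linked RNA. Over 90 tested members the change there was a median of 0.097 times that in knockout 0 (95% bootstrap interval 0.0802 to 0.135). Over the 15 genes known to differ by sex it was 1.36 times. These lists were chosen because they were higher in knockout 0, and the 15 genes because they passed between knockout 1 and the controls. Both ratios partly follow from these choices, so they do not decide whether sex was the cause. They show only that these lists changed far less in knockout 1 than in knockout 0. A smaller epithelial share alone would raise the markers of every other cell type alike, but endothelial markers had a median log2 change of 0.0581 (interquartile range 0.41) against 1.95 for macrophage markers. Podocyte markers had a median of -0.235, but podocytes are themselves epithelial cells, so this median does not bear on that explanation. A smaller epithelial share together with other shifts in cell types is not excluded by these values. A kidney without the knockout under the label of knockout 1 stays open, since Pkd1 there was at 105.7% of the control mean and its transcript level does not check the deletion. A more advanced disease in knockout 0 stays open as well and was not tested.

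The third pattern is the set of 22 genes listed at 0 in every control. Ranked by FPKM times transcript length in the knockout libraries, the 21 with a known length had a median percentile of 99.88, and 19 were in the top 1% of 18065 genes, with Ass1 (97.27) and Sycp3 (43.53) outside it. Estimates that failed at loci with many fragments would give such ranks. Yet the top 1% held 181 genes, and knockout 1, the deepest library by estimate, had a value above 0 at each of the 22. The number of fragments alone therefore does not account for the zeros, which followed the groups. A difference in processing between the groups was not tested and cannot be told apart from genotype here. A biological loss of all these transcripts from the controls was not tested.

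Of the 10 splits of the 5 libraries into 3 and 2, the real one called 802 genes and the highest of the others 1. With 10 splits no share under 0.05 can be reached.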
